A study of Mus musculus with 10 samples.

How the data were processed

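RNA from epididymal white adipose tissue of 10 mice, 5 on normal chow and 5 on a high-fat diet, was measured on 10 arrays. Per the labels' protocols, double-stranded cDNA was made from each mouse's total RNA, and biotin-labelled cRNA was transcribed from it. The deposited table holds 1 linear intensity for each of 45101 probe sets and each array. The summary algorithm, the scaling and the scanner are not given in the sources used here. The array medians and means differ, so the authors' intensities were treated as not scaled to a common level. No detection calls were used here, so the lowest intensities carry no statement on whether a transcript was present.

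Groups and replicate numbers were taken from the sample titles. The intensities were raised to a floor at the 5th percentile of all values (0.658) and log2 transformed. The medians of the 10 arrays then differed by 0.613, over a limit of 0.5 set beforehand, so the arrays were quantile normalized. Probe sets were named from the platform annotation that was given, with symbols compared with the RefSeq gene table: 34958 probe sets had exactly 1 gene symbol, 932 had several and 9211 were not listed there, which leaves them unnamed here. No gene was named from a probe set with several symbols. The 64 control probe sets were left out of the tests. For each of 18193 genes the probe set with the highest mean over all arrays was used; for 243 genes another probe set changed past the threshold in the opposite direction to the one used, or to its sign where it did not pass. No coordinates are printed, since the table names no genome build.

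Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit, eBayes with a trend on mean expression, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The 35 gene lists, with 591 members of which 546 were named on the array, were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, were alternatives. Single values were also tested with a 2-sided exact permutation test over all 252 arrangements, whose smallest p is 0.00794. No interval is given for depth, since the number of arrays limits the precision.

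The test, its design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names Cx3cl1, Cx3cr1, Adam10 and Adam17; the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose mean lay above the median of all probe sets; up to 4 members of each list with the largest changes past the threshold, filled to 2 by the smallest p; and genes of a list that a test is about. The alternatives were the values as deposited, centring on array medians, other variance priors, array weights, filters on dim genes, other choices of probe set, another floor, log2(value + 16), the replicate number as a block, and each array left out in turn. Leaving out chow arrays 1 and 2, leaving out chow arrays 1, 2 and 3, and the epididymis and testis list mean as a covariate were added after seeing the data.

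The procedure was tested on simulated data with the means and spreads of the 18193 genes of the high-fat against chow comparison. The changed genes were drawn from those above the median mean. Of 100 simulated changes of 1 on the log2 scale 62% were recovered, and of 100 changes of 2, 90%, with 6 false calls among 158. A simulated list shifted by 1 passed, and 0 of 34 unshifted lists did. The simulated genes vary independently, so this does not test how camera behaves where genes vary together.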

Results

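Gene expression was measured in epididymal white adipose tissue, the fat pad attached to the epididymis, from male C57BL/6J mice. The mice were 8 weeks old at the start and were fed normal chow or a high-fat diet with 60% fat for 8 weeks. Each group held 5 mice with 1 Affymetrix mouse expression array each, so p-values measure the spread between mice. The median probe-set intensity of the arrays ran from 17.9 to 27.4, and the number of arrays limits the precision of every value. All changes are given as the high-fat diet against chow on the log2 scale, with the standard error (SE) of the difference from limma.

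The arrays of the high-fat group were alike and those of the chow group were not. The median correlation between arrays was 0.976 within the high-fat group, 0.859 within the chow group and 0.775 between groups. Transcripts of the epididymis and testis were measured in chow arrays at far higher levels than in high-fat arrays: the mean log2 level of 11 such genes was 8.93 ± 2.21 on chow and 5.28 ± 0.46 on the high-fat diet (SD, n = 5 each). Chow arrays 1 and 2 held the lowest endothelial and adipocyte marker levels of all 10 arrays. The RNA quality controls also differed. The 5' to 3' signal ratio of the actin control was 0.341 ± 0.0731 on chow and 0.614 ± 0.0380 on the high-fat diet, and that of the Gapdh control 0.726 ± 0.123 and 1.05 ± 0.0265 (SD, n = 5 each; 2-sided exact permutation p = 0.00794 for both, the smallest possible, and the same after adjustment over 3 controls).

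**Figure D1:**
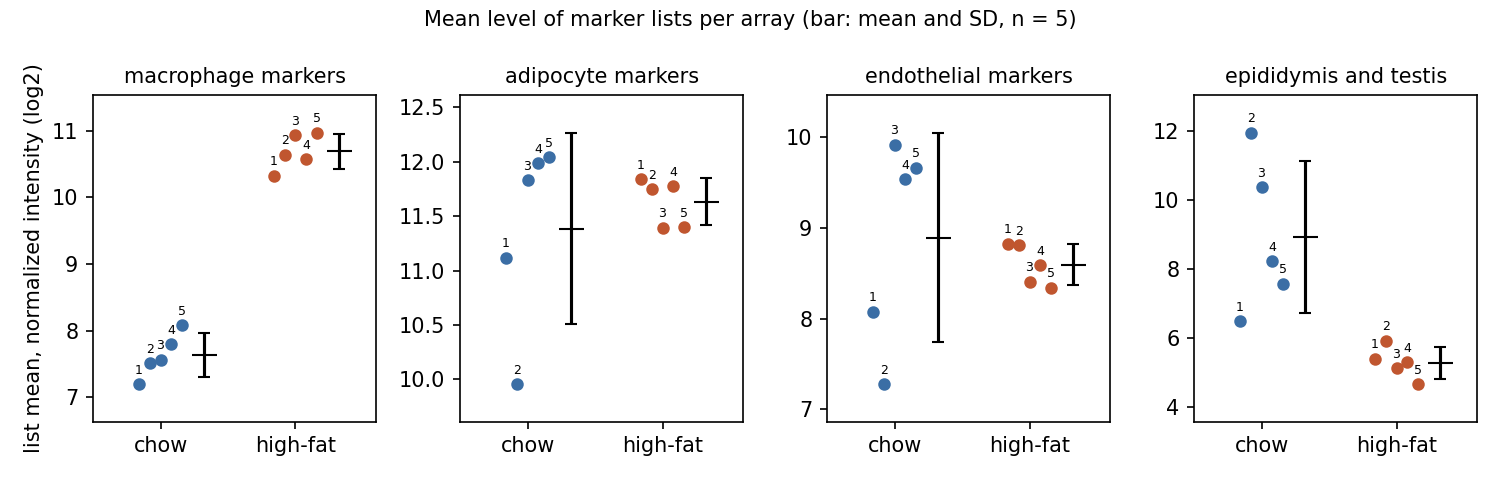
Mean normalized log2 intensity of 4 marker lists in each of the 10 arrays, with replicate numbers beside the points and the group mean and SD as bars. All 5 high-fat arrays lie above all 5 chow arrays for macrophage markers and below them for epididymis and testis markers, while chow arrays 1 and 2 lie lowest for endothelial and adipocyte markers.

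The first comparison concerned Cx3cl1, the chemokine fractalkine, which the study followed in fat as obesity developed, with its receptor and the proteases that shed it. Cx3cl1 fell by 1.59 on the log2 scale on the high-fat diet (SE 0.24, adjusted p = 0.000943), from 6.83 ± 0.53 to 5.25 ± 0.13 (SD, n = 5 each), and all 5 high-fat arrays lay below all 5 chow arrays (2-sided exact permutation p = 0.00794, the smallest possible). Adam17, a protease that releases Cx3cl1 from the membrane, rose by 1.24 (SE 0.15, adjusted p = 0.000236). Adam10, the other such protease, differed by 0.022 (SE 0.15, adjusted p = 0.933). These are the values of the brightest probe set of each gene. The other Adam10 probe sets differed by 1.86, 0.45 and -0.25 and did not pass the threshold. The other Adam17 probe sets rose by 1.49 and 1.15 and passed. Cx3cr1, the receptor of Cx3cl1 on monocytes and macrophages, differed by 0.80 and did not pass the threshold (SE 0.43, adjusted p = 0.206; 2-sided exact permutation p = 0.103, n = 5 each).

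These Cx3cl1 values come from the brightest probe set of the gene. The other 3 probe sets of the gene were dim, differed by 0.33, -0.29 and -0.44, and did not pass the threshold; with the mean of all 4 probe sets the difference was -0.50 (SE 0.36, adjusted p = 0.369). With the mean of the epididymis and testis list as a covariate, chosen after seeing the data, the Cx3cl1 difference was -0.98 (SE 0.33, adjusted p = 0.106). That mean was only 6.49 in chow array 1, against 4.66 to 5.92 on the high-fat diet. The epididymal gene Pate4 (12.95) and the keratin Krt19 (11.71) were nevertheless highest in chow array 1. The covariate thus follows transcripts of other tissue in that array only in part. Cx3cl1 ranked the chow arrays in the same order as the epithelial genes Krt8, Krt18 and Cldn7 did, though not as Krt7 or Krt19 did. Chow arrays 1 and 3 differed little in Cx3cl1 (6.81 and 6.80). A share of the Cx3cl1 signal from epithelium was not tested. Without chow arrays 1 and 2, also chosen after seeing the data, Cx3cl1 fell by 1.3 (SE 0.17, adjusted p = 0.000259) and Cx3cr1 rose by 1.31 (SE 0.34, adjusted p = 0.0126). The chow arrays kept in that fit, 3 to 5, had epididymis and testis means of 10.38, 8.24 and 7.58, all above every high-fat array. Leaving out chow arrays 1 and 2 thus does not remove the difference in these transcripts. Cx3cr1 also passed without chow replicate 2 alone (1.17, adjusted p = 0.0207). Over all alternatives the adjusted p ran from 8.74e-05 to 0.369 for Cx3cl1 and from 0.0125 to 0.374 for Cx3cr1. Cx3cr1 was dim, and over all arrays it differed by 0.37 on the log2(value + 16) scale. Its level was highest of all arrays in chow array 2 (5.30). The other, dimmer probe set of Cx3cr1 differed by 1.37 (limma adjusted p over all probe sets = 0.255).

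**Figure D2:**
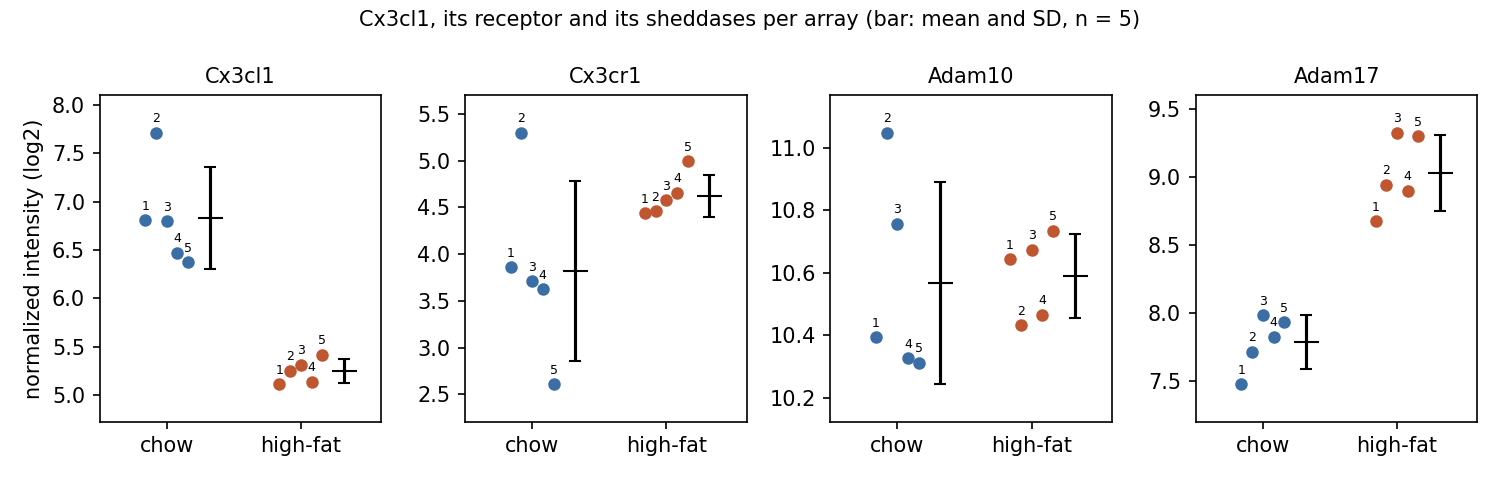
Normalized log2 intensity of Cx3cl1, Cx3cr1, Adam10 and Adam17 in each of the 10 arrays, with replicate numbers beside the points and the group mean and SD as bars. Cx3cl1 lies lower and Adam17 higher in all 5 high-fat arrays than in all 5 chow arrays, and the groups overlap for Cx3cr1 and Adam10.

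Ranked by log2 change above the floor, the 10 largest rises on the high-fat diet included genes of macrophages, and the 10 largest falls included genes of epithelia and of the epididymis. Among genes whose groups did not overlap, the largest rises included Trem2, a lipid-sensing receptor of macrophages (8.85, SE 0.27), Ubd, a ubiquitin-like modifier (6.08, SE 0.24), Mmp12, macrophage elastase (6.08, SE 0.57), Il1rn, the interleukin 1 receptor antagonist (5.99, SE 0.55), and Tph2, an enzyme of serotonin synthesis (9.55, SE 0.55). Gpr50, Vsig8, Cd200r1, Rgs1 and Adam8 completed the 10 rises, with changes of 6.97, 6.34, 5.88, 5.76 and 5.72. The falls were those of Cldn7, a tight junction protein of epithelia (-7.82, SE 0.96), Tpd52l1 (-6.74), the defensin Defb2 (-6.74), the epididymal secretory protein Crisp4 (-6.69) and the fatty acid elongase Elovl2 (-6.5). Cnn1, Ceacam10, Tmed6, ccdc198 and Ly6f followed, with changes of -6.5, -6.43, -6.41, -6.22 and -6.19. Both rankings depend on the floor: with the same genes ranked on the log2(value + 16) scale, 7 of these rises and 1 of these falls were among the 10 largest. On that scale Il1rn and Cd200r1 rose by 3.99 and 3.53, and Tpd52l1, Defb2, Elovl2, Tmed6, ccdc198 and Ly6f had changes of -3.75, -4.47, -3.91, -4.12, -3.83 and -4.12.

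Of 18193 genes tested with limma, 4717 changed at an adjusted p under 0.05, 2338 higher and 2379 lower on the high-fat diet. The share of changed genes that were higher was 49.6%, but 64.8% for the values as deposited and 75.4% with each array centred on its median; the median change of all genes was -0.037, 0.078 and 0.21 in turn. At 2-fold or more, 1463 genes were higher and 1232 lower. The groups did not overlap for 4097 genes, 22.5% of those tested, where chance gives 0.794%. Without chow arrays 1 and 2, 6954 genes changed, 3358 higher and 3596 lower; 4347 of these had changed the same way over all 10 arrays and 0 the opposite way. With the epididymis and testis list mean as a covariate, 1337 genes changed, though this covariate follows transcripts of other tissue in chow array 1 only in part. Of 142 named genes that changed, 36 had a change over 1.5 times that on the log2(value + 16) scale, a limit chosen after the data were seen, and the text gives their values on that scale. On the log2(value + 16) scale Tph2 rose by 6.62, Trem2 by 6.01 and Cldn7 fell by 4.52. The Trem2 rise belongs to the brighter of its probe sets, and the probe set used when those with possible cross-matches were left out gave a difference of -0.48 (adjusted p = 0.550).

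Most general and lipid-associated macrophage markers rose. Of 20 general macrophage markers, 19 rose and none fell, with a median change of 3.09, and the count adjusted over the list alone was also 19. Cd68, a lysosomal glycoprotein of macrophages, rose by 5.17 (SE 0.29), the signalling adaptor Tyrobp by 4.32 (SE 0.21), Adgre1, which encodes F4/80, by 4.19 (SE 0.24), and the integrin Itgam by 3.85 (SE 0.56). The list passed the camera test (adjusted p = 1.12e-20), with an adjusted p = 0.125 with an estimated correlation. Among 13 markers of lipid-associated macrophages, 10 rose and none fell (11 adjusted over the list alone), including Gpnmb (4.86, SE 0.32) and the protease Ctsk (4.63, SE 0.32) besides Trem2 and Mmp12. This list had a camera adjusted p = 3.29e-10, and an adjusted p = 0.125 with an estimated correlation. Of 17 alternative and resident macrophage markers, 8 rose (10 up and 1 down adjusted over the list alone), among them Folr2 (3.16), Chil3 (2.98), the lectin Clec10a (2.72) and the mannose receptor Mrc1 (2.68); the camera adjusted p was 0.000426, and the adjusted p = 0.406 with an estimated correlation. Without chow arrays 1 and 2, 19 general markers rose and 1 fell, 12 lipid-associated markers rose and none fell, and 7 alternative and resident markers rose and 2 fell. The call of the last list was lost with the epididymis and testis list mean as a covariate (adjusted p = 0.0896; range over the alternatives with the preset correlation 7.12e-05 to 0.0896). Itgam and Chil3 rose by 2.23 and 1.62 on the log2(value + 16) scale. The 5' to 3' ratios of the actin control were higher in the same 5 high-fat arrays, with a mean of 0.614 against 0.341 on chow.

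Among chemokine genes past the threshold, more rose than fell. Of 35 chemokine ligands, 15 rose and 3 fell (16 and 4 adjusted over the list alone). The monocyte attractant Ccl2 rose by 4.62 (SE 0.39), Ccl3 by 4.86 (SE 0.52), Ccl9 by 3.48 (SE 0.43) and Ccl24 by 3.47 (SE 0.56). The ligand list had a camera adjusted p = 3.44e-05, and an adjusted p = 0.125 with an estimated correlation. Of 21 chemokine receptors, 8 rose and none fell, the same adjusted over the list alone, including Cxcr4 (3.15), Ccr7 (3.12), Ccr1 (2.96) and Ccr2, the receptor of Ccl2 (2.67). Their camera adjusted p was 0.000258, and the adjusted p = 0.259 with an estimated correlation. With chow arrays 1 and 2 left out, 17 ligands rose and 4 fell, and 9 receptors rose. Ccl3, Ccl24 and Ccr7 were dim on chow, and on the log2(value + 16) scale rose by 2.0, 1.4 and 0.61.

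Inflammatory genes did not all move one way. Of 20 genes of classical activation, 8 rose and 2 fell, the same adjusted over the list alone. The acute phase gene Saa3 rose by 5.56 (SE 0.26), the inflammatory protease Casp1 by 3.52 (SE 0.34) and the cytokine Tnf by 3.34 (SE 0.58), whereas Ptgs2, the inducible cyclooxygenase, fell by 5.36 (SE 0.78, adjusted p = 0.000634). The list had a camera adjusted p = 0.00342, and an adjusted p = 0.259 with an estimated correlation; the call was lost with each array centred on its median (adjusted p = 0.0503; range over the alternatives with the preset correlation 0.00146 to 0.0565). Ptgs2 was highest in chow arrays 1 and 2, as were the epithelial keratins Krt8 and Krt18. Without these arrays 7 genes of the list rose and 2 fell. Tnf was dim on chow and rose by 1.16 on the log2(value + 16) scale. Of 12 interferon response genes, 6 rose (7 adjusted over the list alone), including Zbp1 (1.65), Oas1a (1.6), Ifit2 (1.03) and Mx1 (0.96), with a camera adjusted p = 0.000835 and an adjusted p = 0.259 with an estimated correlation; 6 rose without chow arrays 1 and 2. The changes of Zbp1 and Mx1 were 1.02 and 0.50 on the log2(value + 16) scale.

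Most genes of antigen presentation rose, and some lymphocyte markers did. Of 12 MHC class II and dendritic cell genes, 10 rose and none fell, the same adjusted over the list alone, with Cd74, the invariant chain, at 2.97 (SE 0.21), H2-Ab1 at 2.6 (SE 0.18), the transcription factor Irf8 at 2.54 and H2-DMa at 2.42. Their camera adjusted p was 7.93e-08, and the adjusted p = 0.139 with an estimated correlation. Of 15 T and NK cell markers, Gzma (2.34), Il2rb (1.31), Cd2 (1.11) and Thy1 (0.85) rose, also adjusted over the list alone, with a camera adjusted p = 0.00987 and an adjusted p = 0.174 with an estimated correlation. Of 10 B cell markers, Cd22 (2.65), the immunoglobulin gene Ighm (2.35), Cd79b (1.58) and Bank1 (1.49) rose, also adjusted over the list alone, with a camera adjusted p = 0.0475 and an adjusted p = 0.380 with an estimated correlation. With log2(value + 16) Gzma, Il2rb and Cd2 rose by 1.31, 0.40 and 0.56, and Cd79b and Bank1 by 0.82 and 0.97. Of the MHC class II and dendritic cell list, 10 genes rose without chow arrays 1 and 2 and 1 fell, and 4 T and NK and 4 B cell markers rose. The T and NK call was lost for the values as deposited (adjusted p = 0.131; range over the alternatives with the preset correlation 0.00378 to 0.235) and so was the B cell call (adjusted p = 0.175; range over the alternatives with the preset correlation 0.00447 to 0.344). The B cell call was also lost without chow replicate 1 (adjusted p = 0.0726), chow replicate 2 (0.0659), high-fat replicate 2 (0.0939) or high-fat replicate 4 (0.0752), and with the replicate number as a block (adjusted p = 0.0510).

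Most proliferation and lysosomal genes rose on the high-fat diet. Of 22 proliferation genes, 18 rose and none fell (18 up and 1 down adjusted over the list alone), among them the mitotic kinases Bub1 (2.76, SE 0.31) and Aurkb (2.68, SE 0.28), the survivin gene Birc5 (2.71) and the spindle motor Kif11 (2.56). The camera adjusted p was 4.89e-12, and the adjusted p = 0.130 with an estimated correlation. Of 18 lysosomal genes, 12 rose and none fell, the same adjusted over the list alone, including the glucuronidase Gusb (2.94, SE 0.18), the cathepsins Ctsz (2.74) and Ctsa (1.63), and the proton pump subunit Atp6v1a (1.64). Their camera adjusted p was 1.82e-07, and the adjusted p = 0.130 with an estimated correlation. With log2(value + 16) Bub1, Aurkb and Kif11 rose by 1.81, 1.64 and 1.52. Among proliferation genes 19 rose without chow arrays 1 and 2 and 1 fell, and 13 lysosomal genes rose and none fell.

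Most matrix genes rose, and the level of genes tied to fat mass expansion differed among the chow arrays. Of 24 matrix and fibrosis genes, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with the protease inhibitor Timp1 at 3.12 (SE 0.30), the proteoglycan Lum at 3.08 (SE 0.39), and the collagens Col5a2 at 2.42 and Col1a1 at 2.26. The camera adjusted p was 4.72e-08, and the adjusted p = 0.338 with an estimated correlation. Of 8 expansion genes, 5 rose, the same adjusted over the list alone, including the leptin gene Lep (3.66, SE 0.83), the Wnt antagonist Sfrp5 (3.87, SE 0.86), Mest (2.51) and the natriuretic peptide receptor Npr3 (2.35). Their camera adjusted p was 0.00423, and the adjusted p = 0.481 with an estimated correlation; without chow arrays 1 and 2 it was 0.0739 (range over the alternatives with the preset correlation 0.000485 to 0.391) with 4 genes higher, and 16 matrix genes rose and 1 fell. There Lep rose by 2.62 and Mest differed by 1.47 (adjusted p = 0.0668). The mean of the expansion list was lower in chow arrays 1, 2 and 3 (8.76, 8.48 and 9.38) than in chow arrays 4 and 5 (11.19 and 11.33). In the fit without chow arrays 1, 2 and 3, chosen after seeing the data, its median change went from 1.59 to 0.36 (adjusted p = 0.0511), with Lep at 1.33 and Sfrp5 at 1.44. Of 15 secreted adipose factors, 5 rose and 1 fell, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.122; 0.0434 without chow replicate 4, range over the alternatives with the preset correlation 0.0434 to 0.971): Metrnl rose by 3.11 and Rarres2, the chemerin gene, by 1.23, while Lcn2, a lipocalin, fell by 2.76. Lcn2 ranked the 5 chow arrays in the same order as the mean of the epididymis and testis list did. With the probe set used when those with possible cross-matches were left out Rarres2 differed by -0.46 (adjusted p = 0.402).

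Metabolic lists held genes that rose and genes that fell. Of 17 cholesterol synthesis and sterol-regulated genes, 6 rose and 1 fell, the same adjusted over the list alone, with Dhcr7 at 2.54 (SE 0.35), Insig1 at 2.02 (SE 0.19), the mevalonate kinase gene Mvk at 1.45 and Sc5d at 1.21. Their camera adjusted p was 0.00610, and the adjusted p = 0.481 with an estimated correlation; 12 rose and 1 fell without chow arrays 1 and 2. In lipogenesis 7 of 19 genes rose and 2 fell, the same adjusted over the list alone; Dgat2, which makes triglyceride, rose by 2.34, Me1 by 1.94, Acss2 by 1.72 and Pnpla3 by 1.69 (camera adjusted p = 0.122). In fatty acid oxidation 5 of 15 genes rose and 1 fell, the same adjusted over the list alone, with the dehydrogenases Acadl at 1.04 and Acadm at 0.77, Decr1 at 0.79 and the regulator Ppara at -1.19 (camera adjusted p = 0.131). Among 30 respiratory chain and ATP synthase genes, 4 rose and 5 fell, the same adjusted over the list alone, with Ndufa5 at -0.68, Uqcrc1 at 0.52, Ndufb10 at -0.48 and Atp5o at 0.48 (camera adjusted p = 0.634). Without chow arrays 1 and 2, 8 lipogenesis genes rose and 6 fell, and 7 respiratory chain genes rose and 6 fell. In that fit 5 fatty acid oxidation genes rose and 3 fell, with a median change of 0.024 against 0.28 over all arrays. Decr1 then differed by 0.47 (limma adjusted p = 0.0678). For the values as deposited, fatty acid oxidation (adjusted p = 0.0128), respiratory chain (adjusted p = 0.00236) and lipogenesis (adjusted p = 0.0339) passed as higher lists, and Ndufb10 differed by 0.0027 with each array centred on its median. Fatty acid oxidation also passed without chow replicate 4 (adjusted p = 0.0434; range over the alternatives with the preset correlation 0.0128 to 0.902), and over the same alternatives the range was 0.000114 to 0.946 for the respiratory chain and 0.0339 to 0.484 for lipogenesis.

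The counts for adipocyte and endothelial markers depended on chow arrays 1 and 2. Over all 10 arrays, 0 of 16 adipocyte markers and 0 of 17 endothelial markers passed limma's threshold, also adjusted over the list alone, where 1 adipocyte marker was higher and 1 endothelial marker lower at an unadjusted p under 0.05. The lists did not pass camera (adjusted p = 0.394 and 0.394). The scavenger receptor Cd36 differed by 0.74 (adjusted p = 0.132), the lipase Lpl by 0.23 (adjusted p = 0.369), the endothelial factor Sox17 by -0.96 (adjusted p = 0.104) and Egfl7 by -0.82 (adjusted p = 0.184). Without chow arrays 1 and 2, 16 of the 17 endothelial markers fell, Sox17 by 1.68 and Egfl7 by 1.55, with a median change of -0.95 (camera adjusted p = 7.01e-09; adjusted p = 0.336 with an estimated correlation). The endothelial list also passed without chow replicate 2 alone (adjusted p = 0.00547; range over the alternatives with the preset correlation 7.01e-09 to 0.884). Without both arrays 6 adipocyte markers fell, and the list did not pass (adjusted p = 0.0525; range over the alternatives with the preset correlation 0.0262 to 0.666). In that fit Cd36 differed by 0.16 (limma adjusted p = 0.163) and Lpl by 0.025 (limma adjusted p = 0.852). In insulin and IGF signalling the receptor genes Igf1r and Insr fell by 1.73 and 1.16 and the adaptor Grb14 rose by 1.26. Igf1r ranked the chow arrays in the same order as the epithelial keratins Krt8 and Krt18 did. Insr did not, and its chow levels were lowest in arrays 1 and 2. Adjusted over this list alone 1 gene rose and 2 fell. The 17 genes had a camera adjusted p = 0.478 over all arrays, 0.0439 without chow replicate 2 and 0.010 without both arrays (adjusted p = 0.336 with an estimated correlation; range over the alternatives with the preset correlation 0.00223 to 0.846). In branched-chain amino acid catabolism Acadsb and Aldh6a1 fell by 0.86 and 0.70 and Dld and Pcca rose by 0.76 and 0.76, and adjusted over the list alone 2 genes rose and 2 fell. The 17 genes had a camera adjusted p = 0.645 over all arrays and 0.0217 without both (adjusted p = 0.597 with an estimated correlation; range over the alternatives with the preset correlation 0.0217 to 0.940).

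Some mesothelial markers and some epididymis and testis markers fell on the high-fat diet. Of 12 mesothelial markers, 6 fell and none rose, the same adjusted over the list alone. These included keratins, which epithelia in general express: Krt18 fell by 4.85, Krt8 by 4.15, Krt19 by 3.53 and Krt7 by 2.52. The camera adjusted p was 0.00108, and the adjusted p = 0.380 with an estimated correlation. Of 11 epididymis and testis markers, 4 fell (9 adjusted over the list alone), with a median change of -3.37: the epididymal protease gene Adam7 fell by 5.83, the lipocalin Lcn5 by 4.75, the sperm nuclear protein gene Tnp2 by 4.76 and the sperm tail gene Odf1 by 3.33. Their camera adjusted p was 0.000513, and the adjusted p = 0.380 with an estimated correlation. With log2(value + 16) the Tnp2 difference was -2.28 and did not pass (adjusted p = 0.0695). Leaving out chow arrays 1 and 2, 7 mesothelial and 8 epididymis and testis markers fell. The median change of the epididymis and testis list was then -4.05.

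**Figure D3:**
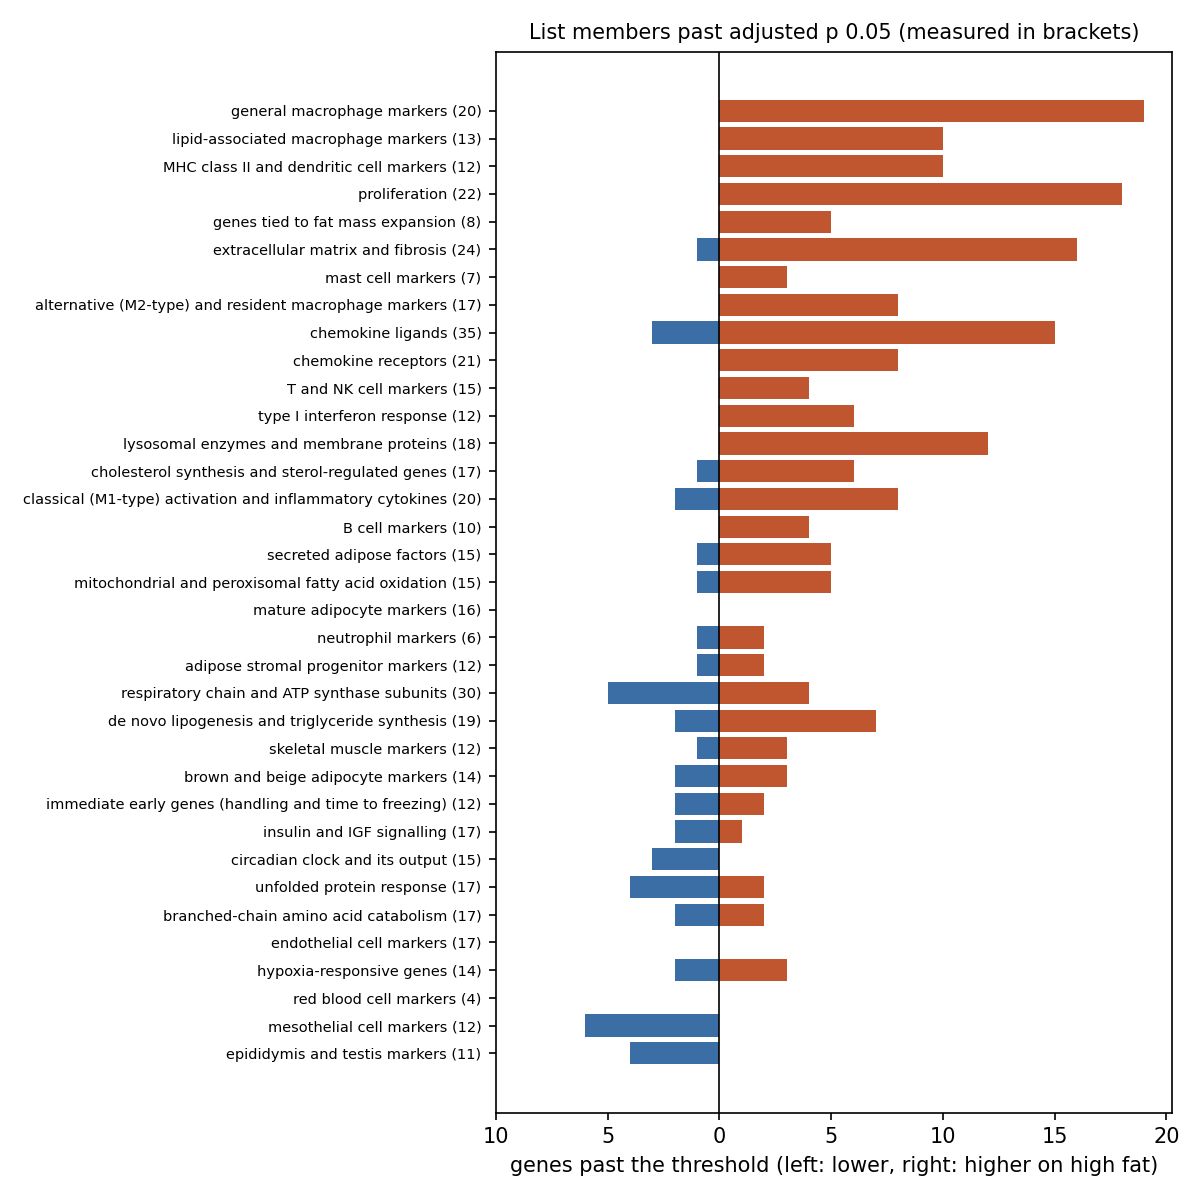
Number of members of each of the 35 fixed gene lists past an adjusted p of 0.05, higher on the high-fat diet to the right and lower to the left, with the number measured in brackets and lists ordered by median change. General macrophage markers have 19 of 20 members higher, and endothelial and adipocyte markers have none past the threshold.

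Of the 35 lists, 17 passed the camera test with its preset correlation of 0.01, 15 as higher and 2 as lower, and 0 passed with an estimated correlation, where 7 higher and 0 lower lists had an unadjusted p under 0.05. With limma's fry, 21 lists passed. Among 100 splits of the 10 arrays into 5 and 5, the real one included, 20 gave 17 lists or more, with 22 the highest of the others.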

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

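The caput marker test, the tests of the Cx3cl1 pattern and the test of the endothelial pattern were chosen after the results were seen, while the second list of epididymal genes and the splits of the arrays were set before their results were seen. That second list was written after the pattern it tests had been noticed.

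Of 376 groups of 5 values, 19 held 1 array far from the other 4, where chance gives about 1 in 20 (18.8); 8 of the 19 were on high-fat array 1. In that array Gpr50 (8.18), Cd36 (13.21), Atp5o (11.04), Car9 (4.96), Ifit2 (7.02), the brown and beige list mean (4.83) and the interferon list mean (6.85) lay below and Mvk (7.14) above the other high-fat arrays, all as log2 levels. High-fat array 4 was high for Uqcrc1 (11.28) and high-fat array 2 low for Dld (9.46). Chow array 1 was low for Irf8 (5.39) and Zbp1 (2.95) and high for Ndufa5 (10.68). Chow array 2 was low for Lpl (12.41) and Cd55 (3.75) and high for Dhcr7 (6.78) and Timp1 (6.18). Chow array 3 was high for Per1 (8.6) and chow array 4 for Myh2 (1.83).

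Signal also differed outside the gene tests. The 18S ribosomal RNA control had a mean intensity of 2209 ± 1060 on the high-fat diet and 536 ± 171 on chow (SD, n = 5 each; 2-sided exact permutation p = 0.00794, the smallest possible, and the same after adjustment over 3 controls). Of 9160 probe sets without a gene symbol here, 728 passed limma's threshold, 320 higher and 408 lower on the high-fat diet.

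Epididymal transcripts were higher in the chow arrays than in the high-fat arrays. A second list of epididymal genes, with 15 of 38 measured and none of them in the first list, had a median change of -4.81 (quartiles -5.37 and -4.21), with 11 lower past the threshold and 0 higher, consistent with epididymal tissue in the chow fat pads. Of its members, Spink8 had a log2 level of 11.9 on chow and 5.99 on the high-fat diet, and Defb42 of 11.69 and 6.26. An effect of diet on these genes in the fat itself cannot be told apart from this: 1 chow array, number 1, had a caput marker mean (4.06) below every high-fat array, and although the bound set for that test was 1 array or more, a single array does not exclude it.

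Cx3cl1 was lower on the high-fat diet, and other tissue and endothelial cells were weighed as its source. Cx3cl1 intensity was extrapolated over chow arrays 3 to 5 to no signal of each of 11 epididymis and testis genes. It stayed at least 1.70 times the highest high-fat array. Each extrapolation is a straight line through the same 3 arrays and assumes that Cx3cl1 rises evenly with the marker. The test therefore cannot decide whether cells followed by these markers are the whole source. With the mean of those markers as a covariate the difference went from -1.59 (SE 0.24) to -0.98 (SE 0.33) and the call ended, as the difference shrank and its error grew, so part of the fall may follow other tissue. In chow arrays 1 and 2, whose endothelial means lay below all high-fat arrays, Cx3cl1 was 1.39 or more (log2) above the highest high-fat array. This argues against fewer endothelial cells as the whole source in these 2 arrays. They also held high Krt18 (11.38 and 11.96, against a mean of 5.31 on the high-fat diet). Other tissue there, together with fewer endothelial cells in chow arrays 3 to 5, was not tested as a joint source. For chow arrays 3 to 5 fewer endothelial cells stay open. Without chow arrays 1 and 2, 5 of 17 endothelial markers fell as much as Cx3cl1. An effect of diet on Cx3cl1 expression per cell was not tested. The actin 5' to 3' ratio also separated the groups (0.272 to 0.456 on chow, 0.557 to 0.643 on the high-fat diet). An effect of RNA quality on Cx3cl1 cannot be told apart from one of diet.

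The endothelial list passed the threshold without chow arrays 1 and 2 and did not pass over all 10. In these 2 arrays the median adipocyte marker lay -1.56 and the median endothelial marker -2.16 from chow arrays 3 to 5, a ratio of 0.722. Both were lower, as dilution by other tissue would give. Equal dilution would give equal shifts, so the test does not settle whether dilution is the cause. A difference in the fat of these 2 mice was not tested.

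For the count of changed genes, 1 of 100 splits of the arrays gave as many, the real one with 4717, and the highest other split gave 0. A random grouping of these arrays thus rarely gives that count, but every other split mixes the diets, which lowers its own count. The splits cannot tell diet from RNA quality or other tissue, which differ along the same grouping. For the lists, 20 of 100 splits gave 17 or more, the real one included, and the highest other split gave 22, so chance is not excluded for the number of lists past the threshold with the preset correlation.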

How the results depend on the processing

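Leaving out chow arrays 1 and 2, leaving out chow arrays 1, 2 and 3, and the epididymis covariate were chosen after seeing the data. Neither fit without chow arrays removes the epididymis and testis transcripts. The mean of that list was 10.38, 8.24 and 7.58 in chow arrays 3, 4 and 5, against at most 5.92 on the high-fat diet. Of 3729 values of 150 named genes under the alternatives, 3416 kept their direction and side of the threshold, 285 no longer passed, 17 newly passed and 11 changed direction; 59 of 142 changed genes passed in every setting. Of 17 lists past the threshold, 14 passed in all 21 planned settings that keep the preset correlation of camera, and 0 passed with an estimated correlation, which was also planned; 0 changed direction. Without detection calls the signal over background of dim genes stays unknown, and their folds depend on the floor. Camera has no robust prior and was not run with one, and Cx3cr1 gave no value without the dimmer probe sets, as it lies there itself.

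Changed genes numbered 2539 at an adjusted p under 0.01 and 2695 at 2-fold or more, both by construction fewer. Genes lower on the high-fat diet numbered 1490 for the values as deposited, 1440 with centring on array medians and 3596 without chow arrays 1 and 2; genes higher numbered 4423 with centring. With the epididymis covariate, whose correlation with diet was -0.787, 1337 genes changed, 852 higher and 485 lower. Cx3cl1 differed by -0.50 with the mean of its probe sets and -0.98 with the covariate. Cx3cr1 passed with array weights (1.17), without chow arrays 1 and 2 (1.31) and without chow arrays 1, 2 and 3 (1.51). No list passed with an estimated correlation (0), where fry gave 21. With each array left out in turn, the values ran from 3652 to 5577 changed genes, 1859 to 2742 higher, 1793 to 2835 lower, -1.7 to -1.37 for Cx3cl1, 0.50 to 1.17 for Cx3cr1 and 16 to 19 lists. Except where stated, the cause was not tested.

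The values showed no pairing of the arrays by replicate number: the correlations of same-numbered deviations ran from -0.0201 to 0.00561. The titles do not say what the numbers mark. The chow arrays differed widely in transcripts of other tissue, which could hide a shared cage, day or batch, so none of these is excluded. No chow array correlated best with the high-fat array of its own number. With the replicate number as a block 3762 genes changed, and of the lists the B cell call alone was lost.

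Values that took the opposite direction are given here. For lists the direction is that of the camera test and the value the median, which can differ in sign; none of these lists passed over all arrays. The cause was not tested. For the values as deposited this was the case for branched-chain amino acid catabolism (-0.021), insulin and IGF signalling (0.085), unfolded protein response (0.078), hypoxia-responsive genes (-0.12), skeletal muscle markers (-0.15). With centring on array medians this was the case for Ndufb10 (0.0027), Tef (0.017), branched-chain amino acid catabolism (0.11), brown and beige adipocyte markers (0.032), insulin and IGF signalling (0.22), unfolded protein response (0.21), skeletal muscle markers (-0.017). With array weights this was the case for mature adipocyte markers (-0.15), adipose stromal progenitor markers (-0.052), unfolded protein response (0.017), immediate early genes (-0.20). Without the dimmest genes this was the case for skeletal muscle markers (-1.04). Without the dimmer genes this was the case for skeletal muscle markers (-1.57). With the mean of all probe sets this was the case for Tef (0.083), insulin and IGF signalling (0.018). Without possibly cross-matching probe sets this was the case for Trem2 (-0.48), Rarres2 (-0.46). Without chow arrays 1 and 2 this was the case for mature adipocyte markers (-0.31), adipose stromal progenitor markers (-0.17), immediate early genes (-0.25). Without chow arrays 1, 2 and 3 this was the case for mature adipocyte markers (-0.43), adipose stromal progenitor markers (-0.12), secreted adipose factors (-0.055), unfolded protein response (0.23), immediate early genes (-0.15). With the epididymis covariate this was the case for Lpl (-0.18), Ddit4 (0.0053), mature adipocyte markers (-0.53), respiratory chain and ATP synthase subunits (-0.088), brown and beige adipocyte markers (-0.35), unfolded protein response (0.58). With each array left out in turn, the direction changed in at least 1 fit for values that ran from -0.041 to 0.14 for Adam10, from -0.11 to 0.20 for adipose stromal progenitor markers, from -0.049 to 0.35 for mature adipocyte markers, from -0.37 to -0.027 for unfolded protein response, from -0.15 to 0.11 for immediate early genes, from -0.39 to -0.11 for branched-chain amino acid catabolism.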

Other observations

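The fit with the epididymis and testis covariate and the fits without chow arrays 1 and 2 or 1, 2 and 3, which the ranges include, were chosen after the data were seen, and the other tests of this part were not. Some clock and stress genes changed, in lists that did not pass as a whole. Over all genes, 4717 of 18193 passed the threshold, which the counts below should be read against. Of 15 circadian genes, Hlf, Per1 and Tef fell, by 1.28, 1.02 and 0.41, also adjusted over the list alone (camera adjusted p = 0.317); Tef had the opposite sign with each array centred on its median (0.017). Among immediate early genes Atf3 rose by 3.6 (SE 0.20) and Fos by 2.99 (SE 0.28), while Ier3 and Nr4a1 fell by 1.73 and 1.49 (2 up and 2 down of 12; 2 and 2 adjusted over the list alone; camera adjusted p = 0.634). In the unfolded protein response Edem1 and Ddit3 rose by 1.13 and 0.63, and Ern1 and Herpud1 fell by 1.15 and 0.79 (2 up and 4 down of 17; 2 and 5 adjusted over the list alone; camera adjusted p = 0.611, and 0.0198 as a higher list with the epididymis and testis covariate, range over the alternatives with the preset correlation 0.0198 to 0.988). Among hypoxia-responsive genes Car9 and Ldha rose by 2.8 and 0.87, and the glucose transporter Slc2a1 and Ddit4 fell by 0.88 and 0.75 (3 up and 2 down of 14; 3 and 5 adjusted over the list alone; camera adjusted p = 0.686). On the log2(value + 16) scale the Car9 rise was 1.32. Of the falls in these lists named here, Hlf, Ern1 and Herpud1 ranked the chow arrays in the same order as the epithelial keratins Krt8 and Krt18. The other named falls did not.

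Other cell types gave mixed lists. The mast cell proteases Mcpt4, Cpa3 and Cma1 rose by 4.07, 3.07 and 2.35 (3 up and 0 down of 7; 3 and 1 adjusted over the list alone; camera adjusted p = 0.180, and 0.0191 with the mean of all probe sets, range over the alternatives with the preset correlation 0.0191 to 0.574). Of the neutrophil genes S100a8 and Csf3r rose by 4.83 and 1.45, and Ltf, also a secretory product of epithelia, fell by 4.27 (2 up and 1 down of 6; 2 and 1 adjusted over the list alone; camera adjusted p = 0.394). Among brown and beige markers Otop1 rose by 5.05 (SE 0.22) and Cox7a1 by 1.31, and Slc27a2 and Tbx1 fell by 4.21 and 2.04 (3 up and 2 down of 14; 4 and 2 adjusted over the list alone; camera adjusted p = 0.611). Among progenitor markers Pi16 and Cd55 rose by 1.7 and 1.66 and Cd24a, which epithelia also express, fell by 3.11 (2 up and 1 down of 12; 3 and 1 adjusted over the list alone; camera adjusted p = 0.837). Cd55 was low in chow array 2 (3.75), and without chow arrays 1 and 2 it rose by 0.91. The muscle genes Pvalb, Myh2 and Myh1 rose by 3.43, 2.76 and 1.32 and Tnnc2, highest in chow array 1, fell by 4.17 (3 up and 1 down of 12; 3 and 1 adjusted over the list alone; camera adjusted p = 0.634). Of 4 red blood cell genes 0 passed limma's threshold, also adjusted over the list alone, and 0 at an unadjusted p under 0.05, Slc4a1 differing by -0.59 and Alas2 by -0.58 (list camera adjusted p = 0.611). With log2(value + 16) Mcpt4, Cpa3 and Cma1 rose by 1.46, 1.93 and 1.41, Csf3r by 0.83, Otop1 by 3.06, Myh2 by 0.58 and Myh1 by 0.36, Tbx1 fell by 0.70, and the Tnnc2 difference was -2.74 and did not pass (adjusted p = 0.0519). In some of these lists the signs of median, mean and test differ: the camera direction was higher for the brown and beige (median -0.025, mean 0.20), immediate early (-0.027, 0.27), progenitor (0.081, -0.15) and muscle lists (0.020, -0.099).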
